A study of Mus musculus with 8 samples.

How the data were processed

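The series holds 8 RNA-seq libraries of mouse cells labelled DC2.4, 4 labelled Blank and 4 labelled mLCAP, prepared per the labels from poly(dT)-enriched mRNA. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned with HISAT2 2.2.1. The read counter, the genome build and the annotation behind the files are not given in the sources used here. The authors deposited one table per library with 55487 genes and, per the file headers, a read count, an FPKM and a TPM for each gene. A further deposited table gives the number of read pairs per library (counts), and the GC content and the share of bases of quality 30 or more in percent, per the file headers.

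The deposited read counts of the authors, computed from alignments and not scaled to depth, are treated here as estimated counts (expected counts). They are whole numbers, so no rounding was needed, but over single-transcript genes with at least 200 counts they stood in a fixed ratio to FPKM times transcript length within 1%, for 98.2 to 98.6% of genes per library. They summed to 3.24 to 3.32 times the read pairs, and 1 counted read pair was taken as 4 counts, an assumption that was not tested. The deposited FPKM values of the authors served for an alternative test, and the deposited TPM values of the authors for the number of genes detected. Each of the deposited tables gave 1 gene a dash in place of a number, and that gene was left out. Gene names, types and positions were taken from GENCODE M21 on GRCm38, which named 55141 of the IDs (99.4%). Whether the library protocol kept the strand is not stated, so genes that overlap in opposite directions cannot be separated, and near-identical copies may share reads.

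Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. The comparison of mLCAP with Blank used edgeR's quasi-likelihood F test with TMM scaling and the default low-count filter, without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 17157 genes. The standard error of a log2 fold change was its size divided by the square root of F. Levels are given as CPM of the deposited counts, as mean and SD over 4 libraries. A count of 0 was given an upper limit of 3 read pairs, taken as 4 counts each, over the library's total. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

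The 33 gene lists, the comparison, its test, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, groups whose ranges do not overlap and a proper symbol, 17 genes set in advance, and up to 4 called members of each list. In cell type and quality lists it also took the member with the highest level. Not every gene taken by the rule is named. Among the list members so chosen, the text gives mainly those whose call was kept without each library in turn; others are named with the effect of leaving out single libraries. That selection was made after the values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 3 tested genes, and again with an estimated correlation, on ranks and with fry. Library measures were compared by 2-sided exact permutation tests over all 70 arrangements, adjusted over 7 measures. Genes of cell identity named beyond the rule, and Gm29216, were chosen after their values were seen. Lists of leukocyte and mesenchymal genes and 5 further lists were written after the first results.

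Alternatives were DESeq2 size factors, library totals, other low-count filters, a block by replicate number, the Wald test of DESeq2, limma-voom, limma on FPKM, an adjusted p threshold of 0.01, a test against a 2-fold change, and each library left out in turn. Chosen after seeing the data were counts divided by 4, a correction for GC content and length, leaving out Blank replicates 1 and 2 together, and the number of genes changed at least 2-fold on FPKM. Other groupings were tested by refitting all 35 splits of the 8 libraries into 4 and 4. The fit was tested on simulated data with 200 changed genes, all with an average above 1 CPM. Of these it recovered 86.6% at a 2-fold change and 55.2% at 1.5-fold, with 8% of calls false. Changes below that level were not simulated, and far more genes were called in the data, so these shares need not hold there.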

Results

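RNA was sequenced from mouse cells labelled DC2.4, the name of a dendritic cell line, in 8 libraries enriched for polyadenylated RNA. The labels put 4 libraries in the group Blank, used here as the control, and 4 in the group mLCAP, in which the cells were kept for 24 h with mLCAP, a vaccine preparation with several adjuvants. Per the labels, its dose corresponded to 85.8 ng/mL of cGAMP, a cyclic dinucleotide that activates the sensor STING, and 63.6 µg/mL of lysate protein. The libraries held 39838954 to 63233078 read pairs, and the deposited gene counts summed to between 131193858 and 206526090 per library. Between 12673 and 13143 genes per library had a TPM of at least 1. The labels do not say that the replicates were separate cultures, so p-values of single genes and library measures rest on the spread between these samples, which may be technical. The camera p-values at the preset correlation of 0.01 compare a list with other genes and treat genes as nearly independent. The estimated correlation reached 0.56 in a called list, oxidative phosphorylation.

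Many genes that mark dendritic cells and other leukocytes were almost without counts in all 8 libraries. Of the 19 genes of the dendritic identity list fixed in advance, 10 had a mean under 1 CPM, 2 of them without a count. A mean over 10 CPM was reached by 6 of the 19, among them Cadm1 at 76.4 CPM in Blank. Itgax, which encodes the integrin CD11c, and the class II genes H2-Aa, H2-Ab1 and H2-Eb1 had 0 counts in each library, and the highest count of Cd74, the class II invariant chain, was 31 in any library. A count of 0 allowed up to 0.0581 to 0.0915 CPM, depending on the library. Of 16 leukocyte genes chosen after their values had been seen, 14 had a mean under 1 CPM, and Ptprc, Tyrobp, Vav1, Rac2 and Cd52 had no count at all. Of a second list of 25 leukocyte genes, fixed before those values were seen, 20 had a mean under 1 CPM, while Arhgdib at 250 CPM and Ptpn6 at 51.6 CPM were the highest of the other 5. By contrast, 19 of 22 genes of mesenchymal cells had a mean over 10 CPM, with Sparc at 735 CPM, Serpinh1 at 478 CPM and the transcription factor Twist1 at 177 CPM. Of the 11 genes of the fibroblast list fixed in advance, 4 had a mean over 10 CPM and 4 a mean under 1 CPM, with a median of 1.76 CPM. Irf8, a transcription factor of the dendritic lineage, was measured at 8.01 CPM in Blank and 7.93 CPM in mLCAP. The libraries are therefore described only as cells labelled DC2.4.

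**Figure D1:**
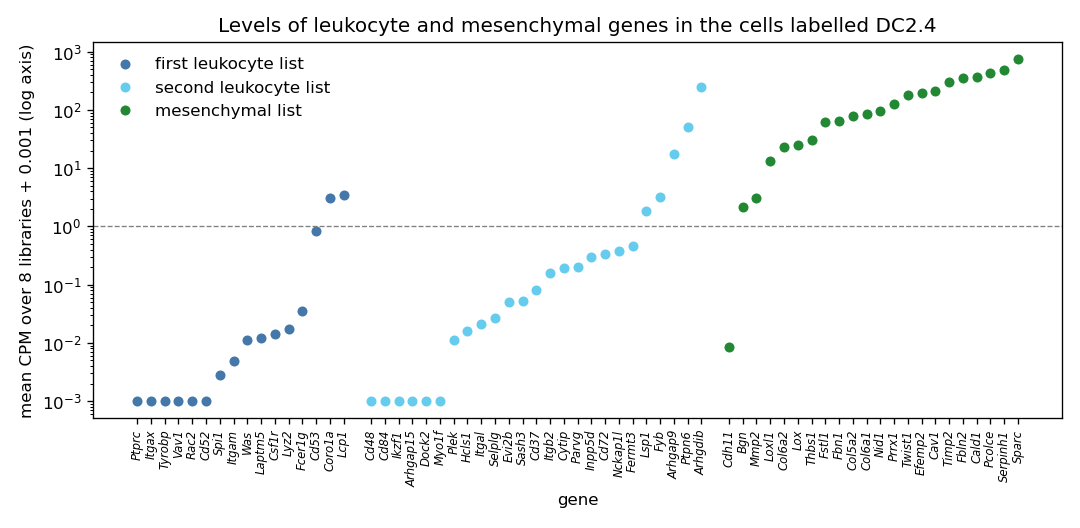
Each point is the mean CPM over the 8 libraries (log axis, with 0.001 added) of 1 gene of the first leukocyte list, the second leukocyte list or the mesenchymal list. The dashed line marks 1 CPM, which 14 of 16 and 20 of 25 leukocyte genes lay under, and 19 of 22 mesenchymal genes lay over 10 CPM.

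The single comparison that the groups allow asks how the transcriptome of these cells differed after 24 h with mLCAP. The labels give that time for mLCAP only, so whether Blank was matched in culture time is not known. Changes were ranked by the rule among called genes with a mean of at least 5 CPM, since some called genes below that level rose more. The largest rises so ranked were in Ndufa4l2, a relative of a respiratory chain subunit, in Il33, an alarmin cytokine, and in Cyp1b1, a cytochrome P450. Ndufa4l2 was 9.83-fold higher, from 6.34 ± 2.47 CPM in Blank to 62.4 ± 5.34 CPM in mLCAP (SD, n = 4 each). Il33 was 8.03-fold higher, from 1.76 ± 0.382 to 14.2 ± 2.71 CPM, and Cyp1b1 was 7.54-fold higher, from 8.47 ± 1.55 to 63.9 ± 8.54 CPM. The largest fall so ranked was in Pmepa1, a feedback inhibitor of TGF-beta signalling, which was 5.74-fold lower, from 16.9 ± 0.662 to 2.94 ± 0.346 CPM. Angptl4, a secreted inhibitor of lipoprotein lipase, was 3.22-fold lower, and Tnfrsf12a, the receptor of the cytokine TWEAK, was 2.71-fold lower.

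Among genes with a mean of at least 5 CPM taken by the rule, the other 5 of the 8 largest rises were in Enpp2 (log2 fold change 2.11 ± 0.14, SE), Klhl24 (1.99 ± 0.18), Tcim (1.89 ± 0.19), Tiparp (1.86 ± 0.14) and Lcn2 (1.84 ± 0.12). Further falls were in Trmt61a (-1.40 ± 0.16), Rrp12 (-1.25 ± 0.15), Ccn2 (-1.14 ± 0.14) and Aen (-1.12 ± 0.08). For each of these genes the CPM ranges of the groups did not overlap, which was a condition for taking them and is no further support. The adjusted p was 5.54e-05 for Ndufa4l2, 2.54e-05 for Il33, 9.32e-06 for Cyp1b1 and 4.72e-06 for Pmepa1. On GRCm38, Ndufa4l2 (ENSMUSG00000040280) lies on chromosome 10 from 127514967 to 127517154, and Pmepa1 (ENSMUSG00000038400) on chromosome 2 from 173224458 to 173276533. Il33 lies on chromosome 19 from 29925114 to 29960718, and Cyp1b1 on chromosome 17 from 79701537 to 79715061.

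**Figure D2:**
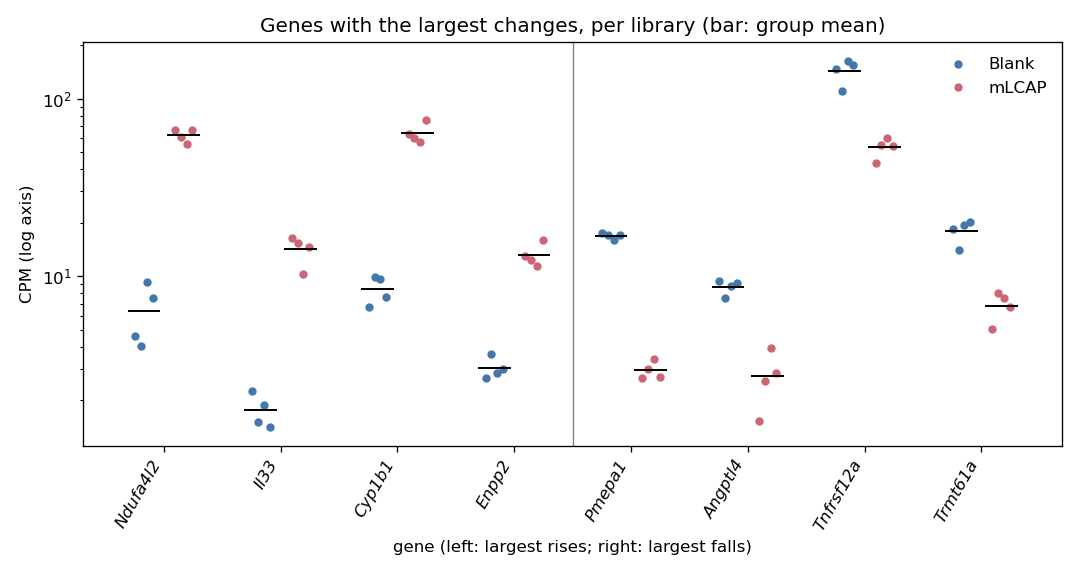
Points give the CPM (log axis) of each library, 4 libraries per group, with a bar at each group mean. Shown are the 4 genes with the largest rise and the 4 with the largest fall among those the rule ranked, with a mean of at least 5 CPM. Ndufa4l2 lay near 62.4 CPM in mLCAP against 6.34 CPM in Blank, and Pmepa1 near 2.94 against 16.9 CPM.

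Of 17157 genes tested with edgeR, 4021 changed, 1947 of them rising and 2074 falling. At least 2-fold changes were called for 374 genes, of which 316 rose and 58 fell. That number was 20 in a test against a 2-fold change, 239 with a filter of 1 CPM and 63 with limma on log2(FPKM + 1). It was 414 with the Wald test of DESeq2 and 473 with limma-voom. The number of changed genes was 2671 without Blank replicate 4, 2453 without mLCAP replicate 1 and 2567 without mLCAP replicate 4, and the number changed at least 2-fold was 601 without Blank replicate 2. Genes of low GC content were higher in mLCAP: the median log2 fold change was 0.30 in the tenth of genes with the lowest GC content and -0.11 in the tenth with the highest.

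Genes induced by type I interferon were lower in mLCAP. Isg15, a ubiquitin-like protein, fell from 235 ± 22.7 to 125 ± 13.1 CPM (log2 fold change -0.92 ± 0.09, adjusted p = 0.000346). Cxcl10, a chemokine for T cells, fell from 203 ± 41.9 to 136 ± 16 CPM (-0.58 ± 0.14, adjusted p = 0.0133), and Ifi35 fell by 0.80 ± 0.12 on the log2 scale. Of the 44 tested members of the list, 1 rose and 19 fell (3 and 22 adjusted over the list alone), with a median log2 fold change of -0.31 and a camera adjusted p of 1.61e-06. The list gave adjusted p = 0.408 with an estimated correlation. The member that rose was Ifit2 (0.42 ± 0.13), whose call was lost when any single library other than Blank replicate 2 was left out (adjusted p from 0.0661 to 0.106). Ifit1 had a log2 fold change of 0.08 ± 0.14, and Ifnb1, the gene of interferon beta, was measured at 0.413 ± 0.185 CPM in Blank and 0.333 ± 0.298 CPM in mLCAP, neither past the test, and Ifit1 was at -0.12 with a correction for GC content and length.

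Among 17 interferon-inducible GTPases, 1 rose and 4 fell (1 and 4 adjusted over the list alone), including Igtp (-0.84 ± 0.09) and Ifi47 (-0.78 ± 0.17). The list missed the threshold (median -0.25, adjusted p = 0.077), with adjusted p = 0.657 with an estimated correlation, but passed it with no low-count filter (0.0293) and with a correction for GC content and length (0.00364, median -0.34, with 0 rises and 7 falls). It also passed without Blank replicate 3 (0.0152), Blank replicate 4 (0.00903) or mLCAP replicate 4 (0.017). In the cGAS-STING list, 1 of 19 tested genes rose and 5 fell (2 and 5 adjusted over the list alone), among them Samhd1, a nucleotide hydrolase (-0.42 ± 0.06), and the list adjusted p was 0.348. Sting1 itself had a log2 fold change of -0.05 ± 0.07, and 0.07 with a correction for GC content and length, neither past the test.

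Class I antigen presentation was lower in part. Of its 21 tested genes, 0 rose and 8 fell in edgeR (0 and 8 adjusted over the list alone, and no rise at an unadjusted p under 0.05 or in DESeq2), with a median of -0.22 and a camera adjusted p of 0.00365, but adjusted p = 0.513 with an estimated correlation. Psmb10, a subunit of the immunoproteasome, fell from 124 ± 19.3 to 58.4 ± 8.03 CPM (-1.09 ± 0.13), and Tapbpl, a peptide editor, fell by 0.62 ± 0.09 on the log2 scale. The class I gene H2-K1 (-0.15 ± 0.11) and its partner B2m (0.24 ± 0.13, and -0.05 with a correction for GC content and length) were not past the test. Only 3 of 15 class II genes could be tested, and 1, Ifi30, fell (1 adjusted over the list alone, list adjusted p = 0.491). The call of Ifi30 was lost without Blank replicates 1, 3 or 4 or mLCAP replicates 1, 2 or 3, each left out alone (adjusted p from 0.057 to 0.0982).

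Inflammatory genes moved in both directions. Nos2, the inducible nitric oxide synthase, rose from 22.8 ± 3.23 to 75.7 ± 6.45 CPM (1.73 ± 0.11, adjusted p = 2.54e-05), Ptgs2, the inducible prostaglandin synthase, rose by 1.23 ± 0.16, and the cytokine Il6 rose from 31.4 ± 9.1 to 65.9 ± 9.78 CPM (1.07 ± 0.18, adjusted p = 0.00273). Csf1, a growth factor of macrophages, fell from 537 ± 9.25 to 318 ± 3.37 CPM (-0.75 ± 0.05). Of 25 tested NF-kB targets, 7 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.28 and a camera adjusted p of 0.00365, but adjusted p = 0.408 with an estimated correlation. Cytokines and chemokines had 8 rises and 3 falls among 23 tested genes (8 and 4 adjusted over the list alone, list adjusted p = 0.491). Toll-like receptors and adaptors had 4 rises and 3 falls among 19 (4 and 3 adjusted over the list alone, list adjusted p = 0.929), with Tlr4 at 0.87 ± 0.14 and its adaptor Myd88 at -0.58 ± 0.08.

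Of 18 tested genes of dendritic cell maturation, 2 rose and 6 fell (3 and 7 adjusted over the list alone, list adjusted p = 0.341). Socs2, an inhibitor of cytokine signalling, rose by 0.78 ± 0.17, and Il15ra fell by 0.89 ± 0.15, both from under 4 CPM in Blank. The checkpoint ligand Cd274 fell from 3.43 ± 0.564 to 2.29 ± 0.5 CPM, a call lost without Blank replicates 1, 2 or 3 or mLCAP replicates 1, 2 or 4, each left out alone (adjusted p from 0.0549 to 0.123). Cd86, Il12b and Il1b had 0 counts in every library, and Cd80 had at most 4 counts, so no difference was detectable in them at this depth. Cd40 (0.63 ± 0.57), Ccr7 (0.66 ± 0.76) and Tnf (0.52 ± 1.33) were not past the test, all from 0.13 CPM or less in Blank, though Tnf passed it without Blank replicate 3 (adjusted p = 0.0143), the only Blank library with a count for it. Of 9 tested uptake receptors, 1, Clec9a, rose (1 adjusted over the list alone, list adjusted p = 0.343). Clec9a, also the largest of 3 rises among 14 dendritic identity genes (4 rises and 1 fall adjusted over the list alone, list adjusted p = 0.447), had at most 6 counts in a Blank library and 34 to 44 counts in the mLCAP libraries, and it fell below the filter of DESeq2.

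Genes of glycolysis and the hypoxia response were higher in mLCAP. Bnip3, a mediator of mitophagy, rose from 53.8 ± 5.74 to 168 ± 16.1 CPM (1.64 ± 0.10, adjusted p = 1.93e-05), and Ndrg1 rose from 253 ± 20.8 to 709 ± 78.9 CPM (1.49 ± 0.09). Of the 27 members, 15 rose and 0 fell in edgeR (16 and 0 adjusted over the list alone, and no fall at an unadjusted p under 0.05 or in DESeq2), with a median of 0.27. The camera adjusted p was 3.15e-06, but adjusted p = 0.248 with an estimated correlation. Oxidative phosphorylation had a median of -0.15 over 30 genes, of which 0 rose and 1, Ndufa4, fell in edgeR (0 and 0 adjusted over the list alone, 1 and 6 at an unadjusted p under 0.05, 0 and 3 in DESeq2). The call of Ndufa4 was lost without Blank replicates 1, 3 or 4 or mLCAP replicates 1, 2 or 4, each left out alone (adjusted p from 0.0578 to 0.114). The list's camera adjusted p of 0.0308 became adjusted p = 0.657 with an estimated correlation, and the list's call was lost without Blank replicate 1 (0.192), Blank replicate 3 (0.13), mLCAP replicate 1 (0.079) or mLCAP replicate 2 (0.0693). On all libraries it was lost with a correction for GC content and length (0.094, median -0.076), with a filter of 1 CPM (0.0848) and with fry (0.303).

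Cholesterol biosynthesis fell across most of its pathway. Of 24 genes, 20 fell and 0 rose in edgeR (21 and 0 adjusted over the list alone, and no rise at an unadjusted p under 0.05 or in DESeq2), with a median of -0.40 and a camera adjusted p of 1.14e-10, but adjusted p = 0.248 with an estimated correlation. Fdps, which makes farnesyl diphosphate, fell from 215 ± 36.1 to 120 ± 12.1 CPM. In the list of cholesterol efflux and lipid storage, 3 of 18 tested genes rose and 4 fell (4 and 5 adjusted over the list alone, list adjusted p = 0.491), with the fatty acid synthase Fasn at -0.83 ± 0.08 and the nuclear receptor Pparg at 0.57 ± 0.14.

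Genes of the lysosome rose more often than they fell. Of 30 tested members, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.000563, but adjusted p = 0.513 with an estimated correlation. Ctsl, a cysteine protease, rose by 0.63 ± 0.07 on the log2 scale, Lamp2, a membrane protein of lysosomes, rose by 0.68 ± 0.11, and Atp6v0c, a proton pump subunit, fell by 0.34 ± 0.08.

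Cell cycle genes were lower, with 2 rises and 17 falls among 35 (3 and 21 adjusted over the list alone) and a median of -0.24. The camera adjusted p was 0.00013, but adjusted p = 0.248 with an estimated correlation. Cdc6, a licensing factor of DNA replication, fell from 86.3 ± 15 to 43.9 ± 6.27 CPM (-0.98 ± 0.14), and cyclin Ccne1 fell by 0.95 ± 0.13, whereas the mitotic kinase Bub1 rose by 0.59 ± 0.14. Mki67, a marker of cycling cells, had a log2 fold change of 1.01 ± 0.37 that missed the threshold (adjusted p = 0.0748) but passed it without Blank replicate 2 (adjusted p = 0.00495). The p53 targets had 8 rises and 6 falls among 23 (11 and 6 adjusted over the list alone, list adjusted p = 0.341), with Trp53inp1 at 1.28 ± 0.28.

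The unfolded protein and integrated stress response fell as a list, with 3 rises and 12 falls among 26 genes (3 and 13 adjusted over the list alone), a median of -0.19 and a camera adjusted p of 0.00332, but adjusted p = 0.513 with an estimated correlation. The chaperone-associated genes Sdf2l1 (-0.66 ± 0.16) and Creld2 (-0.51 ± 0.08) fell, and Vldlr, a lipoprotein receptor, rose (1.13 ± 0.14). Heat shock proteins had 2 rises and 6 falls among 15 (2 and 6 adjusted over the list alone, list adjusted p = 0.119), with Hspa4l at 0.95 ± 0.14 and Hsph1 at -0.74 ± 0.11. The NRF2 list had 7 rises and 1 fall among 22 (8 and 3 adjusted over the list alone, list adjusted p = 0.52), with the quinone reductase Nqo1 at 0.93 ± 0.10, and its median of -0.06 differed in sign from its mean of 0.10 and its upward test. Metal and iron genes had 5 rises and 3 falls among 15 (6 and 3 adjusted over the list alone, list adjusted p = 0.341), with the metallothionein Mt2 at 1.24 ± 0.10. Inflammasome and necroptosis genes had 4 rises and 2 falls among 18 (5 and 3 adjusted over the list alone, list adjusted p = 0.341), with the caspase Casp4 at 0.78 ± 0.15. Immediate early genes had 3 rises and 1 fall among 16 (3 and 1 adjusted over the list alone, list adjusted p = 0.491), with Klf2 at 0.41 ± 0.10 and Ier2 at -0.41 ± 0.10.

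**Figure D3:**
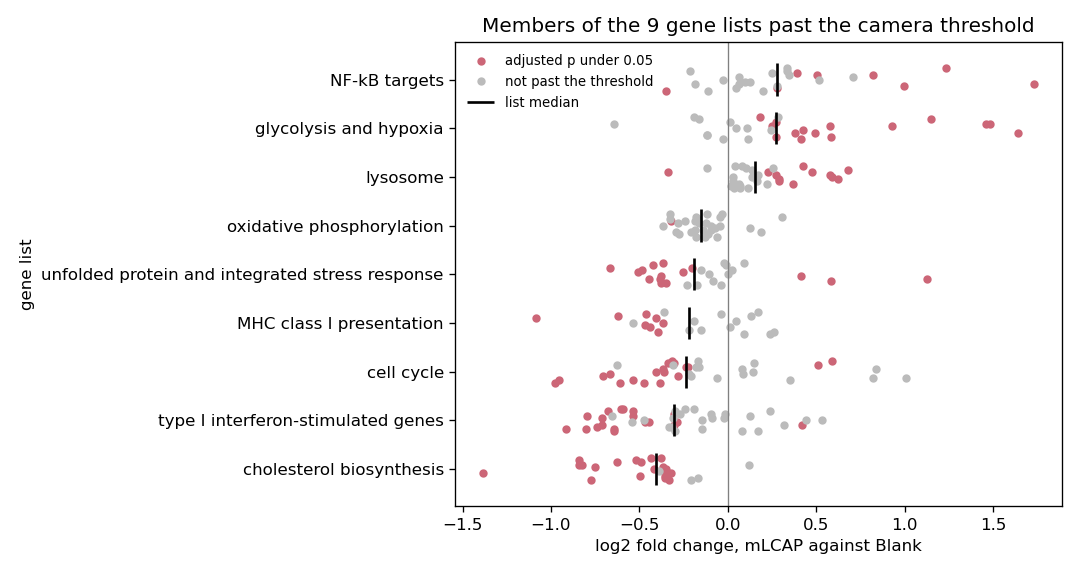
Each point is the log2 fold change (mLCAP against Blank) of 1 tested member of the 9 gene lists past the camera threshold, coloured by whether the gene passed the edgeR threshold, with a bar at the list median. The medians run from -0.40 for cholesterol biosynthesis to 0.28 for NF-kB targets.

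Markers of other cell types gave no list past the camera threshold, whereas fry, which does not compare a list with other genes, called the macrophage (adjusted p = 0.0169), melanocyte (0.00554), fibroblast (0.0177) and neutrophil and mast cell lists (0.0449). Of 8 tested macrophage genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone, list adjusted p = 0.52), with the lysosomal protein Cd68 rising from 12.3 ± 1.49 to 33.9 ± 7.65 CPM and Mpeg1 at -0.67 ± 0.14. Fibroblast genes had 4 rises and 1 fall among 9 (4 and 1 adjusted over the list alone, list adjusted p = 0.181), with the collagen gene Col3a1 at 0.55 ± 0.07, fibronectin Fn1 at 0.45 ± 0.10 and the smooth muscle actin Acta2 at -0.74 ± 0.07. The melanocyte list had 2 rises, Mitf and Gpnmb, among 3 tested genes (2 adjusted over the list alone, list adjusted p = 0.333). Mitf lost its call without Blank replicates 1, 3 or 4 or mLCAP replicates 1, 2 or 4, each alone (adjusted p up to 0.0936). Gpnmb lost its call without Blank replicates 3 or 4 or mLCAP replicates 1 or 4, each alone (up to 0.0837). No gene passed the edgeR threshold among 8 epithelial (0 adjusted over the list alone, list adjusted p = 0.929), 4 neutrophil and mast cell (0 adjusted over the list alone, list adjusted p = 0.491) or 2 erythroid genes (0 adjusted over the list alone), nor did any at an unadjusted p under 0.05 or in DESeq2, although Krt18, an epithelial keratin, was present at 170 ± 22.9 CPM in Blank. The epithelial median of -0.02 differed in sign from the mean of 0.14, and the camera and fry tests pointed in opposite directions. The only lymphocyte gene tested, Trac, fell from 0.584 ± 0.172 to 0.277 ± 0.0807 CPM (1 adjusted over the list alone), a call lost when any single library other than Blank replicate 1 was left out (adjusted p from 0.0502 to 0.158). The lymphocyte and erythroid lists held fewer than 3 tested genes and were not tested as sets.

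Mitochondrially encoded genes took 3.35 ± 0.69% of counts in Blank and 4.77 ± 0.54% in mLCAP (SD, n = 4 each), a difference that did not pass after adjustment (2-sided exact permutation p = 0.0286, adjusted p = 0.0667 over 7 library measures). The ranges did not overlap (2.33 to 3.87% in Blank, 4.46 to 5.58% in mLCAP). That p is the smallest that 4 against 4 libraries allow, and over 7 measures it passes only if enough others reach it too. Of the 13 protein-coding genes among them, which form the list, 2 rose (2 adjusted over the list alone): mt-Nd5 (0.90 ± 0.19) and mt-Co1 (0.76 ± 0.13). Of the mitochondrial tRNA genes, 12 rose, 0 fell and 9 were not called, and of the mitochondrial rRNA genes 1 rose and 1 was not called. Among these tRNA genes only mt-Ty (adjusted p = 0.0405), mt-Ts1 (0.0379) and mt-Tp (0.0414) kept the call with a correction for GC content and length. The rRNA gene mt-Rnr1 lost its call with that correction (0.0614). In mLCAP replicate 4, mt-Nd5 reached 4770 CPM, against 2814 to 2946 CPM in the other mLCAP libraries. The value of mt-Co1 is uncertain, since its nuclear copy Gm29216 moved by 0.75 and the 2 may share reads. The camera adjusted p of the list was 0.205, and the list passed without Blank replicate 4 (0.0475) or mLCAP replicate 1 (0.0495). With a correction for GC content and length its median turned from 0.09 to -0.29, with 2 rises and 7 falls. Of 32 ribosomal protein genes, 1, Rpl4, rose (0 adjusted over the list alone, list adjusted p = 0.815), a call lost without Blank replicate 4 (0.0529) or mLCAP replicate 1 (0.0617). Their median of -0.02 differed in sign from their mean and test, and the list passed in the downward direction without Blank replicate 2 (adjusted p = 0.0326).

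The sequencing measures separated the groups without passing after adjustment. The GC content of read 1 was 51.21 ± 0.16% in Blank and 50.78 ± 0.10% in mLCAP, and the share of bases of quality 30 or more was 95.96 ± 0.05% and 95.66 ± 0.05%, each with an exact permutation p of 0.0286 (adjusted p = 0.0667), the smallest that 4 against 4 libraries allow. Read pairs (exact permutation p = 0.714), ribosomal protein share (0.914) and genes with a TPM of at least 1 (0.143) did not pass. All 9 lists past the camera threshold lost it with an estimated correlation, where 0 lists passed and 3 had an unadjusted p under 0.05, and fry called 19.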

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

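The tests of the second leukocyte list, of a single library behind the interferon genes and of other splits for the single lists were set before their results were seen. The tests of lost genes, GC content, scaling, quality and the splits for the numbers of genes and lists were chosen only after the result was seen.

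In 13 of 242 groups of 4 libraries (5.37%) 1 library stood far from the other 3, measured as its gap to the nearest library over the whole range, and chance gives about 5%. Blank replicate 2 stood apart for Samhd1 (gap over range 0.849), Lamp2 (0.838), Mitf (0.875, at 8.39 CPM against 3.59 to 4.19) and the number of genes with a TPM of at least 1 (0.832). Blank replicate 3 stood apart for Tnf (1.0, at 0.258 CPM against 0 in the others) and Tfrc (0.922), and Blank replicate 1 for Tlr4 (0.890). mLCAP replicate 1 stood apart for Tcim (0.850) and Mpeg1 (0.845), mLCAP replicate 3 for Ifnb1 (0.834, at 0.774 CPM against at most 0.249) and Ptgs2 (0.878). mLCAP replicate 4 was highest for mt-Nd5 (0.933, at 4770 CPM against 2814 to 2946) and for the mitochondrial share of counts (0.909, at 5.58%).

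Most of the listed genes shared by leukocytes lay near 0 in all 8 libraries. A general loss of genes in the counting is argued against, since 0% of 121 genes that every cell uses had no count in any library. These are other genes, so a loss limited to leukocyte genes was not tested. Of the second leukocyte list 80% lay under 1 CPM, exactly the bound set in advance, and 86.4% of the mesenchymal list lay over 10 CPM, which is consistent with the explanation that cells that do not express leukocyte genes gave the RNA. Whether such cells are a changed form of the labelled line or another line was not tested, because the series holds no reference sample. The measured response may therefore be that of cells unlike dendritic cells. However, 6 of 19 genes of the dendritic identity list fixed in advance had a mean over 10 CPM, and so did 4 of 11 fibroblast genes.

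Type I interferon-stimulated genes were lower in mLCAP. A GC or length trend is argued against as the whole cause, because the median was -0.32 with the trend removed, and scaling is argued against by a median of -0.26 with library totals. A single library or a mislabelled sample is argued against only weakly. The lowest Blank library lay above the highest mLCAP library, but by only 0.0689 in mean log2 CPM. The list was taken because it passed between these groups, which favours such a separation. Its median log2 fold change stayed between -0.37 and -0.27 without each library in turn. Of the 35 splits, 1, the real one, gave a median of that size (0.31 against at most 0.26), but the list was taken because it passed in that split, so this leaves chance open. The treatment named by the groups stays open, untested, as does a preparation batch that followed the groups, and the list lost its call with an estimated correlation.

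Genes of low GC content were higher in mLCAP (rank correlation of log2 fold change with GC content -0.35 across 10081 genes, which are not independent replicates). The trend as the cause of the gene calls is argued against, since 83.1% of the 4021 calls were kept with the trend removed. A preparation or sequencing batch that follows the groups cannot be told apart from the treatment, because the base quality also separated the groups (exact permutation p = 0.0286). A trend that follows the treatment alone is open as well: Blank replicate 2, with a rank correlation of -0.31, lay within the mLCAP range of -0.56 to -0.07, but 1 library decides nothing.

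The number of changed genes was as large in 1 of 35 splits, the real one (4021, the highest other 1). The same held for the number changed at least 2-fold (374 against 1). This argues against chance as the source of the grouping, but 35 splits cannot exclude it. Every other split mixes the groups, so any steady difference between them, also a batch, lowers its numbers. Chance stays open for the number of lists, since 4 of 35 splits, the real one included, gave as many (9 in the real one, 10 in the highest other). The size of list medians cannot exclude chance either, because the lists were taken for passing in the real split. The real split gave the largest median, with 1 split as large, for NF-kB targets (0.28, highest other 0.22), lysosome (0.15, 0.13), cell cycle (0.24, 0.18), glycolysis and hypoxia (0.27, 0.19), cholesterol biosynthesis (0.40, 0.28) and the unfolded protein response (0.19, 0.15). Other splits also gave a median as large for class I presentation (3 splits with the real one included, 0.22, highest other 0.30) and oxidative phosphorylation (7 splits with the real one included, 0.15, highest other 0.24).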

How the results depend on the processing

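Chosen only after the data were seen were the tests with counts divided by 4, with a GC and length correction and without Blank replicates 1 and 2, and the number changed at least 2-fold on FPKM. No called named gene and no called list turned direction in any alternative. The number of changed genes, 4021, was 1811 at an adjusted p of 0.01, fewer by construction, and 2453 to 5906 without single libraries (2671 without Blank replicate 4, 2453 without mLCAP replicate 1, 2567 without mLCAP replicate 4). The number changed at least 2-fold, 374, was 239 with a filter of 1 CPM and 237 at an adjusted p of 0.01, where fewer genes can pass. It was 20 in the glmTreat test against a 2-fold change, which is stricter. With limma it was 63 on log2(FPKM + 1) for genes with a mean FPKM of at least 1, and 245 on log2(FPKM + 0.1) without a filter. The test, the input, the filter and the added value all differ there, so no single cause can be given. The number was 281 to 601 without single libraries (601 without Blank replicate 2) and 611 without Blank replicates 1 and 2. The 9 called lists became 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 19 with fry, which does not compare a list with other genes, and were 8 to 11 without single libraries. The number of named genes called was 99, and 74 to 99 without single libraries, totals that include newly called genes. Of the 99 first called, 72 kept the call each time and 27 lost it at least once. A block by replicate number gave 4668 changed genes, 387 at least 2-fold and 9 lists, and the numbers did not pair the samples (correlations of same-numbered libraries from 0.01 to 0.06). Other alternatives left 2791 to 5051 genes changed among those tried on all libraries, and the rising share moved from 48.4% to 56.0% with library totals.

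Results that turned direction were all uncalled at first, and the cause was not tested. The median of Toll-like receptors was -0.0052 with a filter of 1 CPM and 0.0042 in the block by replicate number, where its test pointed the other way, and -0.036 to 0.070 without single libraries. The epithelial list kept its median of -0.020 but turned direction with fry, was -0.0082 with counts divided by 4 and 0.10 with the GC correction, and ran from -0.075 to 0.13 without single libraries. With the GC correction Ifit1 was -0.12, Sting1 0.071, B2m -0.048 and the mitochondrial list -0.29. Without Blank replicates 1 and 2, Tnf was -0.47, the mitochondrial list -0.077 and the ribosomal list -0.18. Without single libraries Ifit1 ran from -0.0079 to 0.25, Ifnb1 from -1.14 to 0.036, Klf1 from -0.53 to 0.058, the NRF2 list from -0.11 to -0.044 and the ribosomal list from -0.14 to 0.052. Tnf had 0 counts in 3 of 4 Blank libraries and at most 40 in any library, so its value rests on few counts.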

Other observations

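All 5 tests of these added gene lists were chosen only after the result was seen, and the lists were written with the changed genes known, so none is independent evidence.

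Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were higher in mLCAP, with 10 rises and 1 fall among 11 tested genes and a median log2 fold change of 0.89. Aldh3a1, an aldehyde dehydrogenase, rose from 143 ± 17 to 367 ± 58.9 CPM (n = 4 each), Xdh, the xanthine dehydrogenase, rose from 270 ± 14 to 499 ± 48.2 CPM, and Ahr itself rose by 1.15 ± 0.13 on the log2 scale. The member that fell was Slc7a5, an amino acid transporter, and the members Ahrr, Cyp1a2 and Lpcat2 were not tested. Tiparp and Nqo1 also belong to the genes named by rule, and Ugt1a6a and Ugt1a6b may share reads (list adjusted p = 0.00578 with an estimated correlation). Genes of ribosome biogenesis were lower, with 0 rises and 17 falls in edgeR among 25 (no rise at an unadjusted p under 0.05 or in DESeq2) and a median of -0.48, led by the methyltransferase Nop2 (-0.93). Targets of MRTF-SRF and YAP-TEAD, regulators that respond to the actin cytoskeleton, had 3 rises and 13 falls among 25 and a median of -0.33, with Srf itself at -0.68 ± 0.08 and the focal adhesion protein Vcl at -0.51 ± 0.07. The rises were in Crim1 (0.42 ± 0.10), Filip1l (0.67 ± 0.19) and Wwc1 (0.39 ± 0.08). Ccn1 (-0.24 ± 0.11), Ankrd1 (-0.27 ± 0.17) and Lats2 (-0.14 ± 0.09) were not past the test. The list pools the targets of both regulators. YAP-TEAD targets were not tested alone, so a fall in them is not shown.

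These lists were tested as sets by camera with an estimated correlation, adjusted over 5 lists. Aryl hydrocarbon receptor targets (higher, adjusted p = 0.00578), ribosome biogenesis (lower, 0.0414) and the pooled targets of MRTF-SRF and YAP-TEAD (lower, 0.0414) passed. Because the lists were written with the changed genes known, passing cannot show that any of these regulators took part in the difference between the groups. FOXO and starvation targets, with 11 rises and 0 falls in edgeR among 18 genes (no fall at an unadjusted p under 0.05 or in DESeq2) and a median of 0.38, did not pass (adjusted p = 0.0775), and neither did TGF-beta targets (2 rises, 3 falls among 20, adjusted p = 0.811) despite the fall of Pmepa1. Whether these differences follow from mLCAP or from a batch that followed the groups was not tested.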
